A study of Mus musculus with 2 samples.

How the data were processed

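Gene expression was measured in sorted mouse bone marrow LSK cells (lineage-negative, Sca-1-positive, c-Kit-positive) with 1 array for decitabine (DAC) and 1 array for phosphate-buffered saline (PBS). Per the labels, total RNA was extracted with the RNeasy Plus Micro kit, mixed with Agilent One Color spike-in controls, and amplified and labelled with Cy3 using the Low Input Quick Amp kit. How many cells were sorted, how much RNA went into the labelling, how many mice stood behind each array and the dose schedule were not given in the sources used here. Per the file headers, the arrays were extracted with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, with probe positions on the mouse build mm9, and both lay on 1 slide.

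The deposited scanner output gives an intensity for each spot. The authors' processed intensity was already background-subtracted and spatially detrended by the scanner software, with a surrogate value for spots not above background, and it was not normalized between arrays. The deposited scanner output also holds the mean intensity of each spot, the median intensity of its local background, and calls for spots well above background, positive and significant, saturated or outlying. The deposited series matrix holds log2 values, 1 column per array, and each column has a median of 0. Set against the log2 processed intensity of the same 55680 probes, the difference between its columns had a slope of 1.00 and a constant offset of −0.60. The scale and the direction of the matrix were thus settled, while the baseline subtracted from each probe stays unknown and the matrix was used for differences between the arrays only.

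From the files, the processed intensity was put on the log2 scale. A probe was left out if its only spot was called non-uniform, which removed 1 of 55681 probes and kept 55680. Spots that departed from the other spots of their probe were left out on that array, and the remaining spots of a probe were averaged on the log2 scale. A probe counted as well above background if at least 50% of its spots were. Each array was scaled by subtracting its 75th percentile over the 25404 probes well above background on both arrays. That subset was the preset fallback, taken because those probes made up 45.6% of all probes. A scaled log2 signal of 0 therefore stands for the 75th percentile. Where several probes belonged to a gene, the probe with the highest mean signal over both arrays stood for it, and a gene was measured if that probe was well above background on both arrays.

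Gene names came from the files and from a gene table of the mouse assembly GRCm38.p6, which was used for names only, since its build differs from that of the probe positions. Of the kept probes, 26761 were named through their transcript accession, 3819 through a current symbol and 639 through a synonym, and 24461 kept the name in the file. This gave 34786 genes or transcripts, of which 18211 were measured on both arrays. Whether a probe lies in an exon or an untranslated region was not given in the sources used here.

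The comparison was the log2 difference DAC minus PBS. With 1 array per group there was no test and no p-value, so genes were counted at 2-fold and at 4-fold. A gene well above background on 1 array only, by any of its probes, was given a lower bound: the difference between its signal there and the higher of its signal on the other array and the lowest signal called well above background on that other array. The error that could be measured was the SD over spots of probes printed 10 times on each array, which covers printing, hybridisation and scanning but neither animals, sorting, RNA extraction nor amplification. The number of arrays limits the precision of every value.

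The genes described by lists belonged to 29 fixed lists. They covered the HSC programme, early myeloid, mature neutrophil, monocyte and macrophage, dendritic cell, erythroid, megakaryocyte, early lymphoid, B cell, T and NK cell, mast cell with basophil and eosinophil, and endothelial and stromal genes. They also covered G1/S and DNA replication, G2/M and mitosis, p53 response, apoptosis regulators, interferon response, antigen presentation, inflammatory, immediate early and heat shock genes. The others were germline, imprinted, DNA methylation machinery, Polycomb complexes, Polycomb targets, Hox cluster, nucleoside uptake and decitabine metabolism, ribosome biogenesis and Myc targets, and oxidative phosphorylation genes. The median difference of a list's measured members was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and a list was set apart if it fell in the lowest or the highest 2.5% of them. These percentiles describe the arrays and are not p-values, because genes are not independent replicates.

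The rule for named genes took the 12 highest and the 12 lowest differences among genes with a proper symbol, a mean signal at or above the median of such genes, and all measured probes differing in the same direction. It also took the 5 largest bounds on each side among genes found on 1 array only, the 4 members of each list with the largest differences, and any list member at least 2-fold by its bound. Tet2, Ezh2, Ezh1, Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Dck, Cda, Cdkn1a, Cdkn2a, Mpo, Kit and Ly6a were always included. List members named outside this rule are identified where they appear, and a few genes that the rule takes are not reported.

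The scaling, the thresholds, the lists, the naming rule and a set of alternatives were chosen before the data were examined. These alternatives were quantile normalization, median centring, intensity-dependent loess with a span of 0.3, scaling on the spike-ins, the series matrix values, normexp background correction with an offset of 50, no background subtraction, the positive and significant call, no filter, only genes at or above the median signal of the measured genes, the mean over a gene's measured probes, list members found on 1 array only added at their bound, and random lists drawn from genes outside all lists. A slide block was also intended but could not be fitted. Scaling over all probes, a common detection limit with its own variants, a test of complex subunits of middle signal, and 20 other seeds for the random lists were chosen after seeing the data.

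The pipeline was tested on simulated data made from the probe signals with the spot noise and the brightness gap of the arrays. For the DAC against PBS comparison, 100% of 100 genes given a log2 size of 1.5 and 100% of 100 genes given a log2 size of 3 were recovered at 2-fold or more in the true direction, among 18200 genes. Of 18000 unchanged genes, 1 reached 2-fold, so the simulation covers spot noise alone. Apart from the simulation, random lists of 20 genes were drawn from the measured differences of the real arrays. They were set apart in 5% of 200 cases with no shift and in 86.5% with a shift of 0.5. The 5% follows from drawing these lists and the random lists from the same genes. It does not cover lists whose members move together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used, with R 4.3.3 and limma 3.58.1 for the normexp correction.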

Results

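Expression was measured in bone marrow LSK cells, the sorted fraction that holds haematopoietic stem cells and multipotent progenitors, from mice carrying a transplanted myelodysplastic syndrome (MDS) of the genotype Tet2KD/KD Ezh2Δ/Δ. Tet2 encodes an enzyme that oxidises methylated cytosine in DNA, and Ezh2 encodes a histone methyltransferase of the Polycomb group. The cells came from secondary recipients 10 weeks after transplantation and 7 weeks after treatment with decitabine (DAC), a cytosine analogue that blocks DNA methyltransferases, or with phosphate-buffered saline (PBS) as the control. There was 1 array per group, so no difference could be checked against a replicate. On the DAC array 31601 of 55680 probes (56.8%) were well above background, and on the PBS array 27007 (48.5%). The 75th percentile of the processed intensity over spots was 217 on the DAC array and 143 on the PBS array, and 0 spots were saturated on either. The SD of a log2 difference expected from repeated spots was 0.26 at low, 0.14 at middle and 0.09 at high signal.

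The comparison of the arrays addressed how stem and progenitor cells of this MDS differ in expression after decitabine. Higher on the DAC array were the stem cell transcription factor Hlf, by 5.60-fold, the DNA methyltransferase Dnmt3a, by 3.20-fold, and Tet2, on both of its measured probes. Other members of the same lists were lower, among them Ctnnal1 (−3.36) and the methyl-CpG binding protein gene Mbd1 (−1.71). The class II antigen presentation genes H2-Aa and Cd74 were 5.74-fold and 5.37-fold higher, and Notch1, a receptor that directs T cell fate, had a log2 difference of 2.21. Lower on the DAC array were Gata1, the master regulator of erythroid and megakaryocyte development, with a log2 difference of −2.02, and Prg2, which encodes eosinophil major basic protein, by 6.62-fold. Tet2 and Notch1 had 2 measured probes each, and the other genes named so far in this paragraph rested on 1. Among genes with a next brightest measured probe, 67.3% of those past 2-fold had the same sign on it. The lists of Hlf and Dnmt3a lay within the range of random lists, at percentiles 73.9 and 89.8. The progenitor genes Mpo, Kit and Ly6a, the last of which encodes Sca-1, had log2 differences of 0.17, 0.12 and 0.07, which became −0.14, −0.19 and −0.24 at their lowest across the alternatives.

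Of 18211 genes measured on both arrays, 1824 were at least 2-fold higher and 1245 at least 2-fold lower on the DAC array, while 83.1% lay within 2-fold. At 4-fold the counts were 338 and 234. The treatment of background moved these counts: normexp correction gave 727 higher and 754 lower at 2-fold and 41 and 60 at 4-fold. No background subtraction gave 722 and 735, and 42 and 58. So did the filter on dim genes, with 3665 and 2196 at 2-fold under the positive and significant call, 5364 and 3038 with no filter, and 479 and 417 among genes at or above the median signal. The median difference was 0.02 and the SD 0.81, and the signals correlated with r = 0.951 across genes, which are not independent replicates. Which side held more genes at 2-fold depended on the scaling. Genes on the higher side made up 59.4% of those past 2-fold, against 49.1% with loess (1488 higher, 1540 lower), 45.8% with median centring (1435 and 1695), 42.4% with quantile normalization (1345 and 1828), 41.9% with the series matrix values (1330 and 1844), 41.8% with scaling over all probes (1329 and 1850) and 32.2% with spike-in scaling (1113 and 2343). Spike-in scaling rested on 1 of 10 spike-in probes, the only one well above background on both arrays. Whether it gives a usable scale was therefore uncertain. The median of all genes shifted by −0.16 with median centring, −0.11 with quantile normalization, −0.20 with the series matrix values and with scaling over all probes, and −0.31 with spike-in scaling. All log2 differences given for genes are DAC minus PBS under the 75th percentile scaling and carry this shift.

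**Figure D1:**
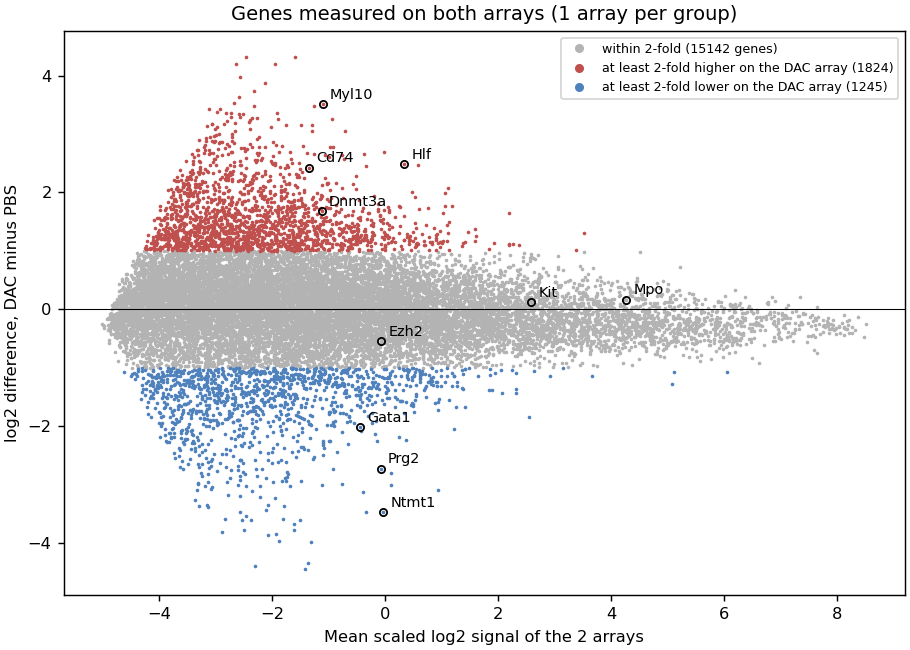
Log2 difference, DAC minus PBS, of each of the 18211 measured genes against its mean scaled log2 signal, with genes at least 2-fold higher in red (1824), at least 2-fold lower in blue (1245), the others in grey and some named genes circled. With the genes split by signal into 3 groups of equal size, 5.80% were at least 2-fold apart at high, 22.1% at middle and 22.7% at low signal.

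The highest differences under the naming rule belonged to Myl10 (NM_021611, 3.51), a myosin light chain gene, and Pxn (NM_133915, 3.48), which encodes the focal adhesion protein paxillin. Next came the sphingosine-1-phosphate receptor gene S1pr3 (NM_010101, 3.16), Hmbox1 (3.06), Ksr1 (3.05), Wdr33 (2.78), Eya2 (2.77), Trub1 (2.65), Thap11 (2.65), Ssbp3 (2.65), Ubl7 (2.60) and Polk (2.57). Hmbox1, Ksr1, Wdr33 and Polk were higher on each of 2 measured probes, and the others rested on 1 measured probe. The lowest differences belonged to Ntmt1 (NM_170592, −3.48), an N-terminal methyltransferase gene, Zfp646 (NM_172749, −3.48), Krt80 (−2.99), Steap3 (−2.80), Prg2 (NM_008920, −2.73), Tyw1 (−2.49), Map1lc3a (−2.45), Cox15 (−2.40), Lactb2 (−2.38), Shtn1 (−2.30), Jmjd6 (−2.30) and Gapdhs (−2.25). Of these, Steap3, a ferrireductase gene, was lower on each of 2 measured probes. The naming rule required the same direction on all measured probes, so such agreement was fixed by the selection. In mm9 the probes lay at chromosome 5, 137173854 to 137176603 for Myl10, chromosome 5, 116004015 to 116004074 for Pxn, chromosome 2, 30678406 to 30678465 for Ntmt1, and chromosome 7, 135025776 to 135025835 for Zfp646.

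With a bound of at least 2-fold, 1256 genes were well above background on the DAC array only and 530 on the PBS array only. The DAC array was also the brighter of the arrays, so more of its dim probes could pass. The largest bounds on the DAC side were those of the imprinted receptor gene Igf2r (at least 51.4-fold higher), the endothelin-converting enzyme gene Ece1 (at least 36.0-fold), Zfp784 (at least 22.3-fold), Gpr107 (at least 20.03-fold) and the interleukin receptor gene Il10ra (at least 19.2-fold). On the PBS side they were those of the stress-induced chaperone gene Hspa1a (at least 42.5-fold lower on the DAC array), Pla1a (at least 25.1-fold), Jaml (at least 24.6-fold), Gpt2 (at least 24.5-fold) and Dnah14 (at least 19.3-fold). Each of these genes was read by 1 probe.

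Of the genes altered in this MDS, Tet2 was past 2-fold and Ezh2 within it. Tet2 had log2 differences of 1.66 (chromosome 3, 133126751 to 133126810, mm9) and 2.22 (chromosome 3, 133126905 to 133126964), and its remaining probe (chromosome 3, 133176421 to 133176479) was not above background on either array. Ezh2 had a difference of −0.55 on its probe (chromosome 6, 47480307 to 47480366). Both arrays carried the same genotype, and whether these probes lie in the altered part of each gene was not given, so they did not check the treatment labels. Among 17 measured genes of the DNA methylation machinery, 4 were at least 2-fold higher (Dnmt3a 1.68, Tet2 1.66, Mbd4 1.44, Tdg 1.21), 2 lower (Mbd1 −1.71, Tet3 −1.55) and 11 between, with a median of 0.22 at percentile 89.8. Dnmt3b had a difference of 0.90, higher on each of its 3 probes, the maintenance methyltransferase Dnmt1 one of 0.33, and its partner Uhrf1 one of 0.03, which turned negative under some alternatives. Tet3 had probes of opposite direction, and its mean over them was 0.20. Hells, a chromatin remodeller needed for DNA methylation, was found on the DAC array only, at least 5.10-fold higher.

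Polycomb genes included 5 of 28 measured complex members at least 2-fold higher, 0 lower and 23 between, with a median of 0.13 at percentile 72.7. The higher members were Cbx2 (2.08), Yaf2 (1.79), Kdm2b (1.56, on both probes), Cbx6 (1.24, on each of 3 probes) and Pcgf5 (1.12, with 1 of 3 probes higher). The H3K27 demethylase gene Kdm6b was found on the DAC array only, at least 8.56-fold higher, as were Phf1 and Pcgf2, by at least 2.86-fold and 2.81-fold. Ezh1, the paralogue of Ezh2, had a difference of −0.11 with probes of opposite direction, and it changed sign between alternatives. Of the 42 known Polycomb target genes on the array 11 were measured: 0 were at least 2-fold higher, 2 lower (Gata3 −1.29, Lhx2 −1.28) and 9 between, with a median of −0.13 at percentile 13.4. Hmga2, an oncofetal chromatin protein gene, had a difference of 0.74. The tumour suppressor gene Cdkn2a was found on the DAC array only, at least 2.25-fold higher, and Isl1 on the PBS array only, at least 2.22-fold lower on the DAC array. Among 10 measured Hox cluster genes and cofactors, 2 were at least 2-fold higher (Hoxa3 1.39, Hoxa6 1.13), 0 lower and 8 between, with a median of 0.00 at percentile 37.6. Hoxb4 and Hoxa5 were found on the DAC array only, at least 3.52-fold and 3.03-fold higher, and Hoxa2 on the PBS array only, at least 2.52-fold lower on the DAC array.

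Germline and imprinted genes were read at few loci. Of 33 germline genes on the array 8 were measured: 0 were at least 2-fold higher, 1 lower (Sycp3 −1.26) and 7 between, with a median of 0.03 at percentile 43.1, or 96.7 with no filter. The germ cell helicase genes Ddx4 and Ddx25 were found on the DAC array only, at least 2.33-fold and 2.73-fold higher, and Hormad1 on the PBS array only, at least 6.87-fold lower on the DAC array. Among 14 measured imprinted genes 0 were at least 2-fold higher, 0 lower and 14 between, with a median of −0.07 at percentile 23.7, or 74.5 with members on 1 array only at their bound. A further 8 imprinted genes were found on the DAC array only, Igf2r, Gab1 (at least 9.73-fold) and Zrsr1 (at least 4.73-fold) among them, while Inpp5f was found on the PBS array only, at least 12.7-fold lower on the DAC array.

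Of 25 measured members of the HSC (haematopoietic stem cell) programme 7 were at least 2-fold higher, 1 lower and 17 between, with a median of 0.14 at percentile 73.9. Hlf (NM_172563, 2.49), the endothelial protein C receptor gene Procr (1.65) and Tie1 (1.31) were among the higher ones, and Ctnnal1 (−3.36) was the lower one. Early lymphoid genes had 4 of 16 measured members at least 2-fold higher, 0 lower and 12 between: Notch1 (2.21, on both probes), the lymphoid transcription factor Ikzf1 (1.65, on 2 of 3 probes), the interleukin receptor gene Il7r (1.37) and the genome organiser Satb1 (1.23). Their median was 0.30, at percentile 97.6. Ccr9, a chemokine receptor gene, was found on the DAC array only, at least 9.54-fold higher. In the megakaryocyte list 4 of 18 measured members were at least 2-fold higher, among them Treml1 (2.66), Itga2b (1.16) and Pf4 (1.04), 0 lower and 14 between, with a median of 0.22 at percentile 79.8.

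Erythroid genes had a median of −0.32, at percentile 2.44, with 1 of 19 measured members at least 2-fold higher (Car1 1.82, with its second probe opposite), 2 lower (Gata1 −2.02, Blvrb −1.01) and 16 between. At any size, 12 members were lower and 7 higher. The lower ones included the globin genes Hba-a1 (−0.39), Hba-a2 (−0.34), Hbb-b2 (−0.82), Hbb-bs (−0.76) and Hbb-bt (−0.63). These closely related genes counted as separate members, so the place of the list among random lists rests partly on them. The erythropoietin receptor gene Epor was found on the DAC array only, at least 2.83-fold higher. Early myeloid genes had 4 of 23 measured members at least 2-fold higher (Igsf6 1.57, Cebpd 1.57, the neutrophil elastase gene Elane 1.56, Cebpa 1.26), 1 lower (Fcgr3 −1.38) and 18 between, with a median of 0.02 at percentile 73.9. Mature neutrophil genes had 2 of 16 measured members at least 2-fold higher (Padi4 1.65, Ltf 1.47), 2 lower (Ngp −1.59, Lcn2 −1.25) and 12 between, with a median of 0.03 at percentile 50.9, which became percentile 3.31 among genes at or above the median signal. The list of mast cell, basophil and eosinophil genes went both ways: of 13 measured members 5 were at least 2-fold higher (Il6st 1.89, Ccl3 1.81, Tpsb2 1.36, Hdc 1.35, Epx 1.20), 4 lower (Prg2 −2.73, Prss34 −1.87, Cma1 −1.38, Cpa3 −1.04) and 4 between, with a median of 0.36 at percentile 89.0. Relative to random lists this median turned to −0.52 with the positive and significant call, to −0.38 with no filter and to −0.43 among genes at or above the median signal. The high-affinity IgE receptor gene Fcer1a was found on the PBS array only, at least 2.85-fold lower on the DAC array.

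Marker lists of other cell types were also read. The dendritic cell list shares members with the early lymphoid list, so it does not read cells outside the sorted gate alone. Of 19 monocyte and macrophage genes 4 were measured, 0 at least 2-fold higher, 1 lower (Cx3cr1 −1.10) and 3 between, with a median of 0.42 at percentile 86.1. Another 10 of them were found on the DAC array only, with bounds of 4.97-fold for Adgre1, which encodes the macrophage marker F4/80, and of 3.84-fold for Lgals3. Of the 6 measured dendritic cell genes 0 were at least 2-fold higher, 0 lower and 6 between (Siglech −0.41, Tcf4 −0.43), with a median of −0.39 at percentile 7.32. Ccr9 and Cd300c from the same list were found on the DAC array only, at least 9.54-fold and 3.93-fold higher. B cell genes had 3 of 16 measured members at least 2-fold higher (Bst1 1.30, Pax5 1.28, Spib 1.07), 2 lower (Cd72 −1.09, Ebf1 −1.08) and 11 between, with a median of 0.25 at percentile 92.0. T and NK cell genes had 4 of 16 at least 2-fold higher (Tcf7 2.27, Cd247 1.83, Lat 1.26, Cd5 1.08), 3 lower (Tbx21 −1.53, Gzmb −1.47, Gata3 −1.29) and 9 between, with a median of 0.11 at percentile 47.5. On 1 array only, Il2rb was at least 7.02-fold higher and Cd3d at least 4.51-fold lower on the DAC array. Endothelial and stromal genes had a median of −0.40, at percentile 2.44, with 1 of 10 measured members at least 2-fold higher (Emcn 1.56), 2 lower (Cxcl12 −1.42, Fn1 −1.03) and 7 between. Among their members on 1 array only, Fabp4 and Col3a1 were at least 5.70-fold and 2.46-fold lower on the DAC array, and Col4a2 at least 4.47-fold higher.

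Genes of the p53 response included 6 of 23 measured members at least 2-fold higher, 2 lower (Rrm2b −1.19, Psrc1 −1.09) and 15 between, with a median of 0.34 at percentile 92.8. Relative to random lists this median was 0.25, against 0.068 with normexp correction and −0.042 at percentile 42.6 among genes at or above the median signal. The translesion polymerase gene Polk (2.57), the cell cycle inhibitor Cdkn1a (1.66), the death receptor gene Tnfrsf10b (1.54) and Ccng1 (1.28) were among the higher ones, and the stress gene Gadd45a was found on the DAC array only, at least 12.7-fold higher. Apoptosis regulators had a median of −0.38, at percentile 2.18, with 0 of 13 measured members at least 2-fold higher, 3 lower and 10 between. The lower ones were Bcl2l2 (−1.74, on both probes), Bad (−1.29) and Bcl2l1 (−1.20), the last pair each with a second probe of opposite direction, and both survival and death genes were in this list. For G1/S and DNA replication, 23 of 25 measured members lay within 2-fold and 1 was lower (Ccne1 −1.43, with its second probe opposite), with a median of −0.15 at percentile 28.4. The thymidylate synthase gene Tyms was found on the DAC array only, at least 3.62-fold higher, and Ccne2 on the PBS array only, at least 2.34-fold lower on the DAC array. For G2/M and mitosis, 2 of 25 were at least 2-fold higher (Cenpe 1.41, Plk1 1.05), 1 lower (the spindle checkpoint kinase gene Ttk, −2.43) and 22 between, with a median of −0.20 at percentile 8.46.

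Genes that handle decitabine and other nucleosides had 4 of 21 measured members at least 2-fold higher, 1 lower and 16 between, with a median of −0.12 at percentile 22.3. It lay at percentile 1.66 among genes at or above the median signal and 65.4 with loess. The higher ones were the efflux pump genes Abcc1 (2.07), Abcc4 (1.84) and Abcb1b (1.06) and the nucleotide hydrolase gene Samhd1 (1.27), and the lower one was the thymidine kinase gene Tk1 (−1.07, with its second probe opposite). Dck, whose kinase activates decitabine, had a difference of 0.13, which turned negative under spike-in scaling (−0.18), scaling over all probes (−0.07), the series matrix values (−0.07) and median centring (−0.03). The deaminase gene Cda was not above background on either array. The nucleoside transporter gene Slc29a2 was found on the PBS array only, at least 3.22-fold lower on the DAC array.

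Antigen presentation genes had 4 of 22 measured members at least 2-fold higher (H2-Aa 2.52, Cd74 2.43, and the peptide transporter genes Tap2 1.38 and Tap1 1.28), 0 lower and 18 between, with a median of 0.12 at percentile 95.4. They were set apart from random lists with quantile normalization, loess, normexp correction and no background subtraction, at 0.29, 0.34, 0.23 and 0.22 relative to those lists, but lay at percentile 82.6 among genes at or above the median signal. Interferon response genes went both ways, with 5 of 31 at least 2-fold higher (Oasl2 1.88, Ifit3 1.77, Oas3 1.45, Stat2 1.45, Ifit2 1.19), 1 lower (Ifit1 −1.79) and 25 between, and a median of 0.01 at percentile 40.9, or 86.9 with no filter. A further 7 were found on the DAC array only, among them Irf7 (at least 9.33-fold) and Oasl1 (at least 4.47-fold). Oas1g was found on the PBS array only, at least 2.81-fold lower on the DAC array. Inflammatory genes had 1 of 15 at least 2-fold higher (the chemokine gene Ccl3, 1.81), 1 lower (Nfkbiz −1.08) and 13 between, with a median of 0.07 at percentile 51.6. Immediate early and heat shock genes had 3 of 23 at least 2-fold higher (Ier2 1.52, Nr4a1 1.23, Egr1 1.02), 3 lower (Klf2 −1.44, Klf4 −1.24, Klf6 −1.13) and 17 between, with a median of −0.24 at percentile 12.8. This place depended on the probes and genes taken, at percentile 96.6 with the mean over a gene's measured probes and 2.08 among genes at or above the median signal. Hspa1a was in this list, as was Egr2, found on the PBS array only and at least 2.44-fold lower on the DAC array.

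Oxidative phosphorylation genes had 0 of 32 measured members at least 2-fold higher, 1 lower (Ndufb2 −1.14, on both probes) and 31 between, with a median of −0.29 at percentile 5.52. Ribosome biogenesis and Myc target genes had 2 of 25 at least 2-fold higher (the spermidine synthase gene Srm, 1.65 on both probes, and Polr1b 1.09), 1 lower (Wdr43 −1.26, with its second probe opposite) and 22 between, with a median of −0.07 at percentile 41.4. Cebpa, Spib, Lat, Cd5, Tpsb2, Hdc, Epx, Cma1, Cpa3, Rrm2b, Psrc1, Stat2, Ifit2, Egr1, Klf6, Mbd4, Tdg, Pcgf5, Abcb1b and the globin genes lay outside the naming rule and were named after their values were seen.

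Against random lists of matched signal, 1 of the 29 lists lay in the top 2.5% (early lymphoid) and 3 in the bottom 2.5% (erythroid, endothelial and stromal, apoptosis regulators), where chance alone would give 1.45 lists. All 4 lay at the edge of the range: with 20 other sets of random lists, early lymphoid genes passed in 12, erythroid genes in 18, endothelial and stromal genes in 18 and apoptosis regulators in 8. Of 14 other settings, 4 shift all genes by a constant and so cannot move a list among random lists. In the remaining 10 settings they passed in 9, 5, 6 and 5, in the same order. Among genes at or above the median signal the erythroid list lay at percentile 29.1 and the endothelial and stromal list, reversed, at percentile 64.3. The erythroid list also holds related globin genes that were all lower, a grouping that the random lists do not match.

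**Figure D2:**
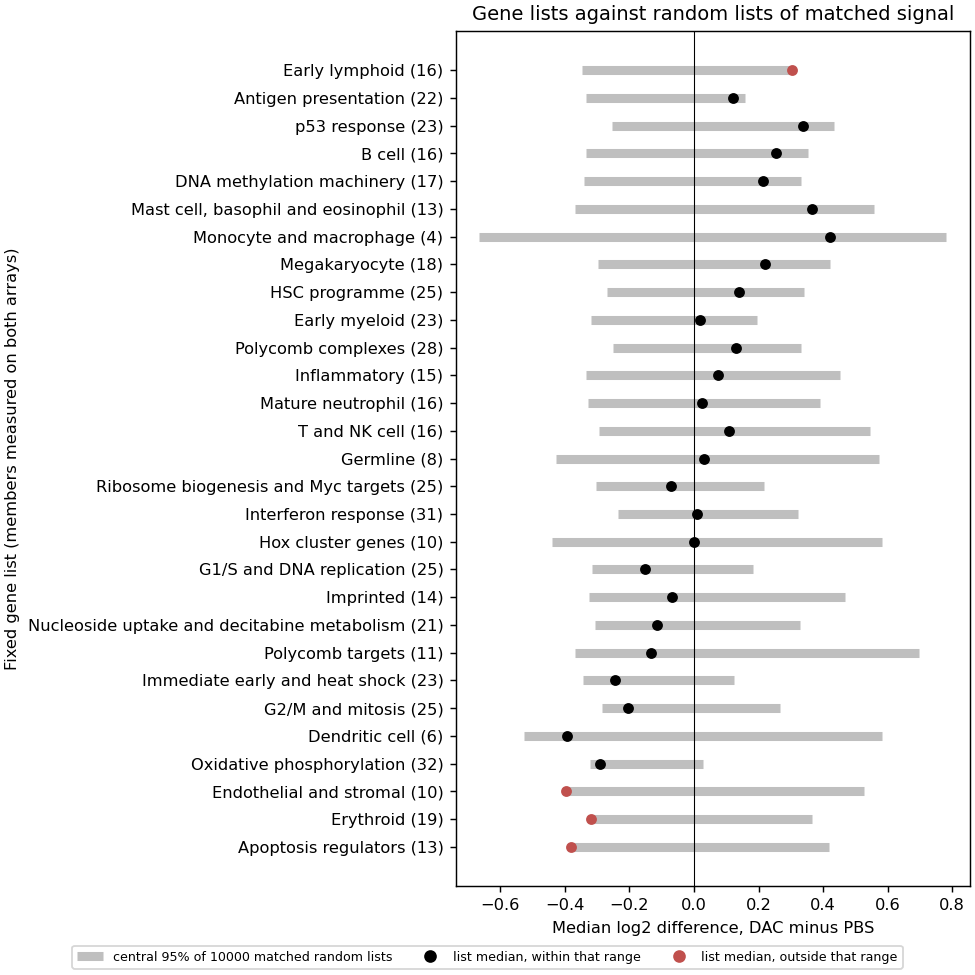
Median log2 difference, DAC minus PBS, of the measured members of each of the 29 lists (points, with the number of measured members in parentheses) and the central range of 10000 random lists matched on signal (grey bars, leaving 2.5% on each side). The medians in red lay just outside their bars, from early lymphoid genes at 0.30 to endothelial and stromal genes at −0.40.

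Different probes of a gene often gave different values. In 4649 genes with at least 2 measured probes, the differences of the brightest probe and the next correlated with r = 0.265 across genes, and 61.3% had the same sign. Of 796 such genes at least 2-fold apart on the brightest probe, 67.3% had the same sign on the next, and 252 were also at least 2-fold apart in the same direction there. Genes whose measured probes all had the same direction numbered 317 at 2-fold or more higher and 161 at 2-fold or more lower.

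**Figure D3:**
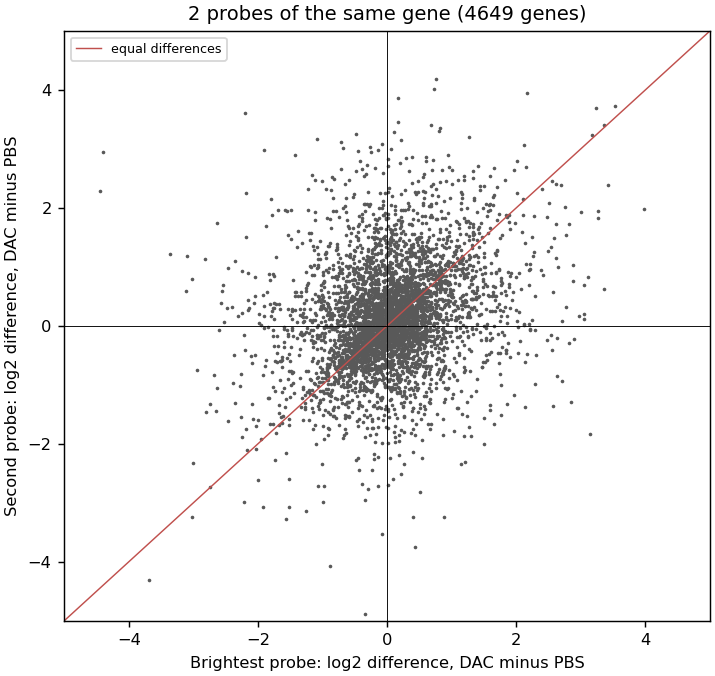
Log2 difference, DAC minus PBS, of the next brightest measured probe against that of the brightest probe for each of 4649 genes, with a line where both are equal. The points spread widely around the line, with r = 0.265 across genes.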

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

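Scaling over all probes, the common detection limit and the 20 other sets of random lists were tests chosen only after the results were seen. No paired analysis was possible because the groups share only replicate number 1, fewer than 2 shared numbers, so no test was run. The slide block was not run, since both arrays lay on 1 slide with 1 array per group. With only genes at or above the median signal, the monocyte and macrophage, germline and Polycomb target lists kept too few members for a value. Signal over background set the limit for dim genes, since 45.6% of probes were well above background on both arrays. The counts of genes on 1 array only stayed within 1.5 times of 1256 and 530 under every alternative run on them, from 939 to 1568 on the DAC array and from 448 to 757 on the PBS array. Of the values of named genes under the alternatives, 863 moved by less than the SD expected from spots, 824 by more, and 1 at least 2-fold gene changed sign.

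The list values here are medians relative to the median of matched random lists, and the cause of each move was not tested unless it is given. Spike-in scaling, which rests on 1 probe, gave 1113 genes at least 2-fold higher and 2343 lower, and 184 and 397 at 4-fold. Quantile normalization gave 209 genes higher and 364 lower at 4-fold, brought erythroid genes (−0.32) and apoptosis regulators (−0.26) back within the range of random lists, and put B cell (0.36) and antigen presentation genes (0.29) outside it. Loess brought erythroid (−0.23), endothelial and stromal genes (−0.43) and apoptosis regulators (−0.28) within the range, put B cell (0.33) and antigen presentation genes (0.34) outside it, and moved the nucleoside list to 0.060. Normexp correction, which adds an offset to every signal and so shrinks differences of dim genes, gave 727 genes higher and 754 lower at 2-fold, and 41 and 60 at 4-fold. With it erythroid (−0.22) and endothelial and stromal genes (−0.23) came within the range, antigen presentation genes left it (0.23), and the p53 response moved to 0.068. Without background subtraction, which also leaves a constant in every signal, the counts were 722 and 735 at 2-fold and 42 and 58 at 4-fold, with erythroid genes at −0.21 and endothelial and stromal genes at −0.22 within the range and antigen presentation genes at 0.22 outside it.

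The positive and significant call admitted more dim genes and gave 3665 higher and 2196 lower at 2-fold, and 1080 and 579 at 4-fold. With it monocyte and macrophage genes left the range (0.83), mast cell, basophil and eosinophil genes reversed (−0.52) and apoptosis regulators came within the range (−0.32). With no filter the counts were 5364 and 3038 at 2-fold and 1972 and 896 at 4-fold, from 34786 genes. Then monocyte and macrophage (0.68) and dendritic cell genes (−0.29) left the range, mast cell, basophil and eosinophil genes reversed (−0.38), apoptosis regulators came within the range (−0.25), and interferon response and germline genes moved to 0.16 and 0.30. Only genes at or above the median signal, 9106 in number, gave 479 and 417 at 2-fold and 46 and 45 at 4-fold. Among them endothelial and stromal genes reversed (0.13), erythroid genes (−0.10) and apoptosis regulators (−0.28) came within the range, and immediate early and heat shock (−0.23) and nucleoside genes (−0.38) left it. In the same genes mature neutrophil, mast cell, basophil and eosinophil, and p53 response genes moved to −0.35, −0.43 and −0.042. The mean over a gene's measured probes brought early lymphoid genes within the range (0.29), moved immediate early and heat shock genes to 0.22 and the nucleoside list to 0.042, and reversed Tet3 (0.20), whose probes had opposite directions. Adding list members found on 1 array only at their bound moved interferon response genes to 0.11 and imprinted genes to 0.13, since most of those members lay on the DAC side.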

Other observations

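The test of other class II genes, the common detection limit with its other limits and scalings, and the test of subunits of middle signal were tests chosen only after the results were seen.

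The spike-in probes, which belong to no gene, were mostly near background. Their 10 probes had a median intensity of 5.89 on the DAC array and 5.21 on the PBS array, and 1 of them was well above background on both.

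Among genes of middle signal the differences between the arrays had an SD of 0.90. The SD expected from repeated spots was 0.153 of that, and averaging 10 spots left an SD of 0.890 times that of probes printed once, which argues against noise between spots. A candidate explanation is a low number of starting RNA molecules and their amplification: 174 measured subunits of 14 constitutive complexes, which cells tend to make in fixed proportions, had an SD of 0.805, against a median of 0.769 in matched random lists (0.655 to 0.894 after leaving out 2.5% on each side), and the 76 of them at middle signal had one of 0.801, against 0.877 (0.698 to 1.08). Subunits as spread as other genes are what that explanation needs, though any other technical step that alters genes at random would give it too. An SD inside the range of random lists is also the usual outcome for a list, so it does not single out that explanation. Whether decitabine acts broadly on such genes was not tested and stays open.

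With no bound on the fold, 3282 genes were well above background on the DAC array only and 977 on the PBS array only, a ratio of 3.36, and the brightness of the whole DAC array could produce such a gap. With 1 common limit on the scaled signal the counts were 2679 and 1225 and the ratio 2.19, just past a bound of 2 that was set, before that ratio was computed, as arguing against brightness. That bound was not decisive, because the ratio ran from 1.46 to 2.69 over 12 combinations of limit and scaling without quantile normalization. Quantile normalization makes the signal distributions of the arrays equal and so holds the ratio near 1 by construction. It gave 0.828, 0.833 and 0.839, with more genes on the PBS side. Brightness and a difference in the RNA therefore cannot be told apart for these genes, and an effect of the treatment stays open.

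H2-Aa and Cd74 were higher on the DAC array, and a few cells of another type that carry class II molecules might bring both. The 6 other class II genes had a median difference of 0.10 (SD 0.54), and 3 of the 6 were higher. A small share of such cells would not show in genes with a high level on the PBS array, and only 2 of the 6 were low there. Both of these were higher, H2-Oa by 0.94 and H2-Eb1 by 0.65, which such cells could also bring. The B cell, dendritic cell, and monocyte and macrophage lists did not rise together, with medians of 0.25, −0.39 and 0.42. On 1 array only, 4 dendritic cell and 10 monocyte and macrophage genes lay on the DAC side, against 1 of each on the PBS side. The median of the 6 genes and the lists that did not rise together met the condition set, after the pattern was seen, as arguing against such cells. That condition was not decisive, because only those 2 class II genes were low on the PBS array, each less than 2-fold higher. The marker lists went both ways, and the hypothesis stays undecided. The sort for lineage-negative cells is meant to remove such cells. A change within the LSK cells after decitabine was not tested.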
